A study of Mus musculus with 2 samples.

How the data were processed

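Total RNA depleted of ribosomal RNA was sequenced from the cytosolic fraction of C57BL/6J bone-marrow-derived macrophages after 75 minutes with 100 ng/ml lipid A, per the labels. There were 2 libraries of 1 group, numbered as biological replicates by the labels, and each library was quantified separately. The deposited readme files state that all tables used genome build mm10 and annotation M21. They also state that the first quantification, a gene table and a transcript table per library, was derived from transcriptome alignments, and the second, a transcript table, directly from the reads. The aligner, the quantifiers, their versions and the strand used in counting are not given in the sources used here.

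The expected counts of both quantifications are the authors' estimates of fragments per gene or transcript, not normalized and not always whole numbers, per the file headers and the values. The TPM values were deposited by the authors and are scaled to the same sum over all entries of each table, per the file headers and the column sums. The posterior SD of each count, another deposited column of the first quantification, was read as the authors' measure of how uncertainly reads were divided among genes. Gene symbols, biotypes and coordinates were taken from GENCODE M21 on mm10, the annotation the readme files name, by versioned gene identifier.

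The gene table held 55536 annotated genes, 22028 of them protein-coding, 97 spike-in sequences and 26248 entries with a bare number as name. The spike-in and numbered entries carry no versioned gene identifier and were left out of library sizes and comparisons. What the numbered entries stand for was not worked out. The spike-ins held 0.251% of the count in replicate 1 and 0.204% in replicate 2, and the numbered entries 0 and 0.950 counts. Library totals over genes were then 55596625 and 50157146. The totals of the second quantification were 65933328 and 62889522. In it, values were summed per gene; 86 genes had no value there. Where a listed symbol named several genes, the gene of highest mean TPM was used; 118 symbols occurred more than once.

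A gene was counted as detected at a mean of 1 TPM. For each of 31 gene lists, the median TPM was placed among the medians of 10000 random lists of the same size drawn from all protein-coding genes. The lists of immediate-early and late genes were compared as medians of log2(TPM + 0.1). Expected counts were rounded to whole numbers and scaled by TMM over genes with a mean count of 10 or more in edgeR 4.0.16 (R 4.3.3), whose common dispersion, fitted with an intercept only, gave the biological coefficient of variation; DESeq2 1.42.0 gave alternative size factors. The ratio of replicate 2 to replicate 1 was computed from scaled counts with 0.5 added. It was taken for genes with a mean count of 10 or more in lists and of 100 or more when counting differences over 2-fold. Where ratios of lists or classes are given, genes with a mean count of 10 or more are called measured. Each list's median ratio was placed among 10000 random lists matched on mean count in 20 bins. Lists in the lowest or highest 2.5% are set apart, a criterion chosen after the data were seen. Random lists draw genes independently, and members of a list may vary together, so these percentiles are not error rates. Ratios carry 95% Clopper-Pearson counting intervals, and where replicate 1 had 0 counts a floor of 3 was used. The depth leaves counting error small for abundant genes, and intervals and floors cover counting error only, since fragments are not independent molecules. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

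For the tests of explanations, a quadratic least-squares trend of the log2 ratio on the log2 length and GC content of each gene's leading transcript was fitted over protein-coding genes with a mean count of 100 or more and subtracted from all lists. The share of a gene's count in transcripts annotated with a retained intron, or for nonsense-mediated decay, was compared between libraries in protein-coding genes with a mean of at least 20 counts in that class, a mean of at least 100 in the gene and counts outside the class in both libraries.

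With 1 group and 2 libraries no test between groups exists and no p-value was computed; errors are SDs over n = 2. The group, the lists, the main comparisons and most alternatives were chosen before the data were examined; the tests of explanations and the criterion for setting lists apart were not. Named are the up to 4 most abundant members of each list, 23 genes fixed beforehand, the 10 most abundant genes and nuclear-encoded protein-coding genes, up to 5 genes in each direction with the largest ratio, and, optionally, members below 1 TPM where a list had 5 or fewer; any other gene was chosen after its values were seen, as its sentence says.

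The calculations were tested on simulated data made from the 2 libraries' means and totals for all 55536 genes. Of 200 genes changed 4-fold, 100% were found in the right direction, and 10 of 9877 unchanged genes of sufficient count were called. A list of 20 raised genes lay at percentile 100 and a list of 20 unchanged genes at 13.4. In separate simulated libraries without changed genes, a biological coefficient of variation of 0.141 was recovered as 0.141. That coefficient was below the 0.176 found between the libraries. The simulated genes varied independently and the raised ones by 4-fold, so smaller shifts shared by a list were not tested.

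Alternatives tried were detection thresholds of 0.5 and 5 TPM and of 10 counts in each library, the second quantification, TPM rescaled over nuclear-encoded protein-coding genes, a background of genes at 1 TPM or more, pseudocounts of 0.01 and 1, means for medians, late and early genes at 1 TPM or more only, DESeq2 size factors and library totals for TMM, count minimums of 10, 100 and 500 and none, a ratio of 1.5-fold, percent of counts for percent of TPM, genes at 10 TPM or more, transcripts of 300 nucleotides or longer, and each replicate left out. Counting only nuclear-encoded protein-coding genes, the ratios of whole RNA classes, the removal of the length and GC trend from all ratios and the limit of 15% on the posterior SD of mitochondrial mRNAs were added after seeing the data. Signal tracks and alignments that the readme files list were not used here.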

Results

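RNA abundance was measured by total RNA sequencing, after removal of ribosomal RNA, in the cytosolic fraction of mouse macrophages grown from bone marrow of the C57BL/6J strain. The cells had been exposed for 75 minutes to 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that Toll-like receptor 4 recognises. All samples belonged to 1 group of 2 libraries, which the labels call biological replicates 1 and 2, each made from 1 µg of RNA. The labels give both the same donor identifier and do not say whether they came from separate animals or cultures, so the SD given here may be partly technical. The first deposited quantification held 55736363 expected counts in replicate 1 and 50259425 in replicate 2. Unstimulated cells, other times and other cell fractions were not analysed here. The values therefore describe which RNAs were present after 75 minutes and how far the replicates lay apart, not what lipid A changed.

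At a mean of 1 TPM or more (transcript abundance corrected for length and scaled to a fixed total), 9154 genes were detected, 9061 in replicate 1 alone and 9199 in replicate 2 alone. Of the 9154, 8657 (94.6%) were protein-coding; 398 genes reached 100 TPM and 25 reached 1000 TPM. In the first quantification the most abundant RNAs were Rn7s2 and Rn7s1, genes for 7SL. This is the RNA of the signal recognition particle, which directs secretory proteins to the endoplasmic reticulum. Rn7s2 (chromosome 12, 69361182 to 69361481, mm10) had 326899 ± 33056 TPM (SD, n = 2) and Rn7s1 (chromosome 12, 69159295 to 69159594) had 324442 ± 32837 TPM. The annotated transcripts of these copies are identical, with 0 differing bases over 300 nucleotides. The split between them is therefore uncertain although the deposited posterior SDs are small, 1.15% and 1.16% of the counts in replicate 1. Together they took 69.8% of TPM in replicate 1 and 60.5% in replicate 2, and 13.1% and 10.6% of counts. In the second quantification they took 29.0% and 18.1% of TPM, with 117806 TPM each. The pseudogenes Gm12895 and Gm12896, chosen after their values were seen, had 189206 TPM each there and 0 in the first. Next in the first quantification came Rn7sk, the RNA that holds the elongation factor P-TEFb inactive (59139 ± 32937 TPM). Rpph1, the RNA of ribonuclease P, followed (34180 ± 12006 TPM). Rmrp, the RNA of the mitochondrial RNA processing ribonuclease, is annotated as 2 genes on the same strand of chromosome 4, from 43492788 to 43493058 and from 43492783 to 43493063, with 12512 ± 8623 and 4393 ± 240.1 TPM. Their posterior SDs in replicate 1 were 0.788% and 1.07% of the count, but the first lies within the second and the second quantification gave 2912 and 2157 TPM, so the division of reads between them is given as uncertain.

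The 10 most abundant nuclear-encoded mRNAs included those of iron storage, lysosomes and secreted macrophage proteins. The ferritin light chain gene Ftl1 (chromosome 7, 45457944 to 45459884) had 6771 ± 526 TPM and the ferritin heavy chain gene Fth1 (chromosome 19, 9980598 to 9985098) had 6293 ± 1057 TPM. Lyz2, which encodes the macrophage lysozyme, had 4169 ± 82.3 TPM. The lysosomal genes Psap (saposin precursor, 3828 ± 951 TPM), Ctsd (cathepsin D, 2703 ± 359.9 TPM), Gpnmb (2093 ± 362 TPM) and Ctsb (cathepsin B, 2009 ± 369.7 TPM) came next, together with the selenium carrier Selenop (2160 ± 90.5 TPM). Tmsb4x, an actin-monomer-binding peptide, had 1869 ± 230.0 TPM, and the lipid carrier Apoe had 1675 ± 647 TPM.

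By class, small noncoding RNAs held 76.5% ± 0.668 of TPM but 14.2% ± 0.735 of expected counts (SD, n = 2). Protein-coding mRNAs other than ribosomal protein, histone and mitochondrial ones held 19.9% ± 0.472 of TPM and 82.0% ± 0.319 of counts. Ribosomal protein mRNAs took 1.71% ± 0.286 of TPM, long noncoding RNAs 0.693% ± 0.0991, pseudogenes 0.518% ± 0.140, mitochondrial RNAs 0.513% ± 0.243 and histone mRNAs 0.0834% ± 0.000374, as the plot of class shares shows. Remaining biotypes held 0.000960% ± 0.0000162. The long noncoding class includes the Rmrp gene annotated as a lincRNA, a short RNA with 4393 ± 240.1 TPM. Most of the TPM of that class therefore came from this gene, whose reads are uncertain as said above. The second quantification gave other shares of TPM: 51.4% for small noncoding RNAs, 38.1% for pseudogenes, 9.10% for the remaining protein-coding mRNAs, 0.710% for ribosomal protein mRNAs, 0.427% for long noncoding RNAs, 0.229% for mitochondrial RNAs and 0.0385% for histone mRNAs. The shares of TPM and of counts differ because TPM divides by effective length, which was 90.0 nucleotides for Rn7s2 in replicate 1 and 1094 for Lyz2. All TPM of mRNAs are lowered by the share that 7SL takes; on a scale over nuclear-encoded protein-coding genes alone, the number of genes detected at 1 TPM or more was 11650.

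**Figure D1:**
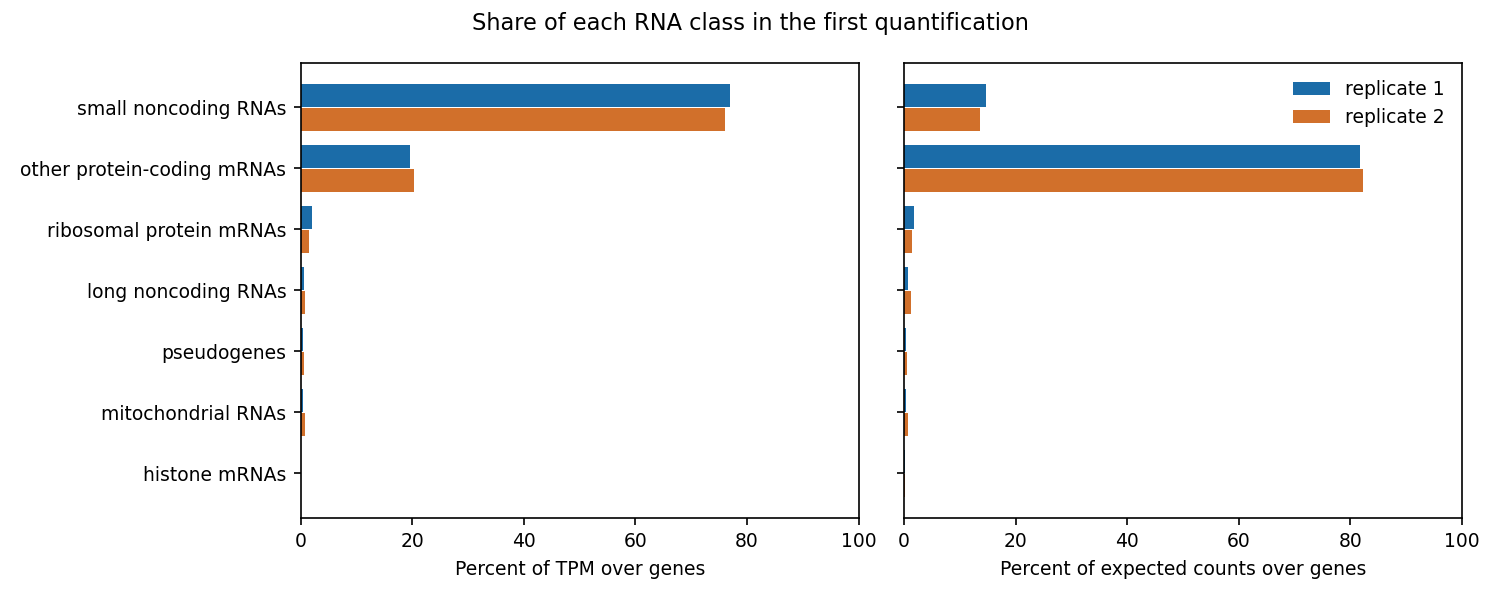
Percent of TPM (left) and of expected counts (right) in each RNA class of the first quantification; each bar is 1 library, replicate 1 blue and replicate 2 orange, and remaining biotypes are not drawn. Small noncoding RNAs averaged 76.5% of TPM and 14.2% of counts, and protein-coding mRNAs other than ribosomal protein, histone and mitochondrial ones 19.9% and 82.0%.

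Inflammatory cytokine and chemokine mRNAs were among the abundant mRNAs at 75 minutes. Tnf, which encodes tumour necrosis factor (chromosome 17, 35199381 to 35202007), had 1402 ± 90.3 TPM, Il1b (interleukin 1 beta; chromosome 2, 129364570 to 129371139) 913 ± 15.4 TPM and Il1a (interleukin 1 alpha) 637 ± 45.2 TPM. Tnfsf9, the ligand of the costimulatory receptor 4-1BB, had 444 ± 47.7 TPM and the anti-inflammatory cytokine gene Il10 had 107 ± 2.25 TPM. Of the 20 cytokines listed, 18 reached 1 TPM; Csf3 (granulocyte colony-stimulating factor, 0.770 TPM) and Il12a (the interleukin 12 p35 subunit, 0.0500 TPM) stayed below. Among chemokines, which recruit leukocytes, 14 of 18 reached 1 TPM. Ccl4 had 1226 ± 237 TPM, Ccl3 1117 ± 319 TPM, Cxcl2 847 ± 2.74 TPM and Ccl2 745 ± 105 TPM, while Cxcl11 (0.530 TPM), Cxcl9 (0.0850 TPM), Ccl17 (0.0500 TPM) and Cxcl5 (0.00500 TPM) were below it.

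Early transcription factors and feedback inhibitors were present almost without exception. All 21 listed genes of the NF-kB pathway and its targets reached 1 TPM, led by the inhibitors Nfkbia (561 ± 14.5 TPM; chromosome 12, 55489410 to 55492647) and Tnfaip3 (A20, 339 ± 8.84 TPM), the surface protein gene Cd83 (268 ± 24.9 TPM) and the nuclear I-kappa-B protein gene Nfkbiz (240.0 ± 25.2 TPM). All 13 genes of mRNA decay and kinase feedback did too, among them Zfp36, which encodes the mRNA-destabilising tristetraprolin (348 ± 1.44 TPM), the MAP kinase phosphatase Dusp1 (264 ± 1.68 TPM), the cytokine-signalling inhibitor Socs3 (221 ± 2.998 TPM) and Zfp36l1 (126 ± 0.735 TPM). Of 16 immediate-early regulators 15 reached 1 TPM, all except Fosl1 (0.0600 TPM). Junb (238 ± 30.1 TPM), the stress-response factor Atf3 (224 ± 59.96 TPM), Klf6 (200 ± 12.4 TPM) and Ier3 (114 ± 19.6 TPM) lay above Egr1 (65.6 ± 6.75 TPM) and Fos (58.8 ± 0.778 TPM). In both libraries the medians of these lists and of the cytokine and chemokine lists were at percentile 100 among 10000 random lists of the same size drawn from all protein-coding genes.

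Interferon genes were also present: Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), had 105.9 TPM in replicate 1 and 48.1 in replicate 2 (77.0 ± 40.9, SD, n = 2), and all 20 listed interferon and interferon-stimulated genes reached 1 TPM. The antiviral gene Rsad2 had 239 ± 152 TPM, the transcription factor gene Irf1 112 ± 7.79 TPM, the ubiquitin-like modifier Isg15 102 ± 49.4 TPM, the antiviral RNA-binding protein gene Ifit2 78.4 ± 42.2 TPM and its relative Ifit1 74.8 ± 58.1 TPM. The list's median was 39.5 TPM in replicate 1 and 25.8 TPM in replicate 2, at percentile 100 in both.

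Of 17 genes known to peak later after lipopolysaccharide 9 reached 1 TPM, and 16 did on the scale over nuclear-encoded protein-coding genes. The list's median was 1.40 TPM in replicate 1 and 2.88 TPM in replicate 2 (percentiles 88.4 and 97.0). Acod1, which makes itaconate (123 ± 17.4 TPM), the cyclooxygenase gene Ptgs2 (62.2 ± 0.247 TPM), the interleukin 12 p40 gene Il12b (27.1 ± 11.4 TPM), the collagenase Mmp13 (24.7 ± 8.85 TPM) and Il6 (6.47 ± 3.57 TPM) were detected. The inducible nitric oxide synthase gene Nos2 had 0.175 ± 0.0778 TPM, from 106 and 47.0 expected counts. On the log2(TPM + 0.1) scale the median of the immediate-early list exceeded that of the late list by 4.66 in replicate 1 and 3.72 in replicate 2 (4.19 ± 0.66, SD, n = 2); among members at 1 TPM or more only, the difference was 1.56. Without a second time point, these levels do not show when any of the genes was induced.

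**Figure D2:**
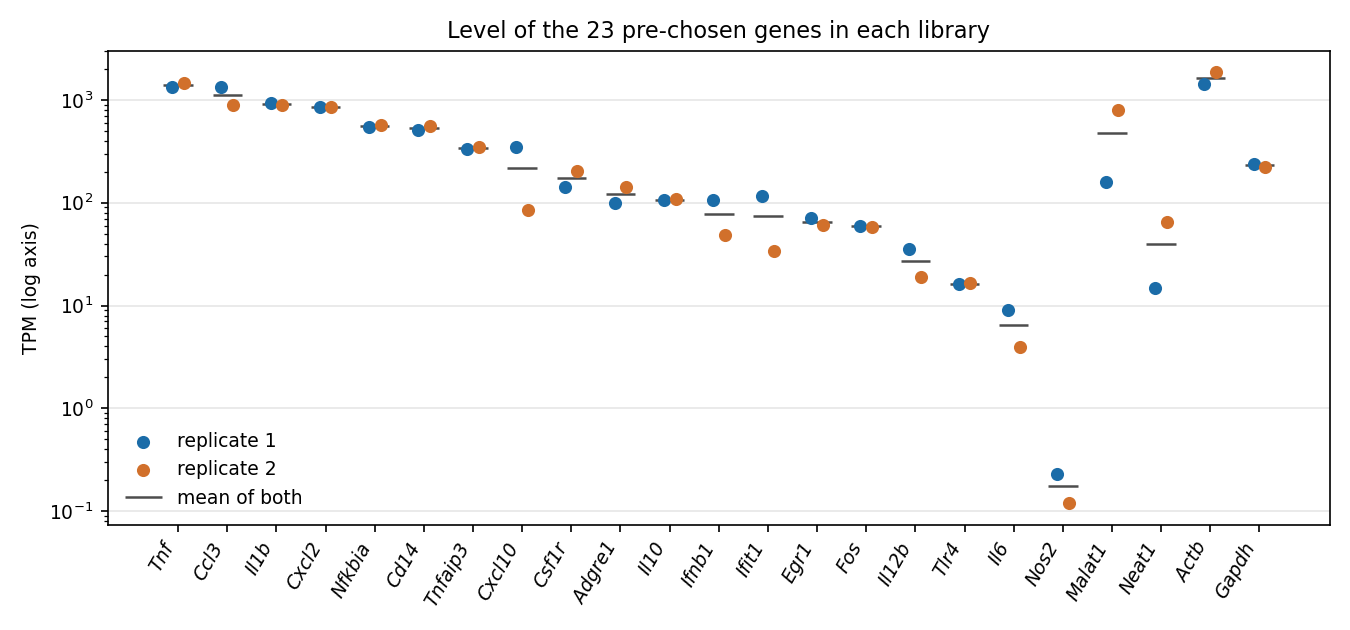
TPM (log axis) of the 23 genes named before the data were examined; blue points are replicate 1, orange points replicate 2, and bars the mean of both. Tnf averaged 1402 TPM and Nos2 0.175 TPM, and Malat1, Neat1, Cxcl10 and Ifit1 lay farther apart between the libraries than Tnf or Nfkbia.

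The lipid A receptor complex was expressed, with 21 of 23 genes of the receptor and its signalling at 1 TPM or more. Cd14, the co-receptor that hands lipid A to the complex, had 532 ± 38.1 TPM and Tlr4 itself (chromosome 4, 66827584 to 66930284) 16.3 ± 0.375 TPM; Tab1 (0.705 TPM) and Lbp, a serum protein made mainly by liver (0.355 TPM), were below. The transcription factor gene Irf5 (41.2 ± 4.82 TPM), the adaptor Tab2 (25.1 ± 0.283 TPM) and the kinase gene Irak2 (22.2 ± 0.438 TPM) were the highest after Cd14, all above Tlr4. Of 20 other pattern receptors 17 reached 1 TPM, including the lipopeptide receptor Tlr2 (133 ± 4.65 TPM), the inflammasome sensor Nlrp3 (120.2 ± 16.6 TPM), the beta-glucan receptor Clec7a (114 ± 5.37 TPM) and Clec4e (75.8 ± 8.45 TPM). Tlr5 (0.515 TPM), Tlr12 (0.0300 TPM) and Tlr11 (0.0250 TPM) did not.

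All 16 listed macrophage identity genes were at 1 TPM or more, with a list median of 90.3 ± 17.2 TPM. Besides Lyz2, the signalling adaptor Tyrobp had 648 ± 12.1 TPM, the endosomal marker Cd68 597 ± 88.3 TPM, the pore-forming Mpeg1 554 ± 134 TPM, the growth factor receptor Csf1r 173 ± 44.6 TPM and Adgre1, which encodes F4/80, 121 ± 31.1 TPM. All 20 lysosome genes reached 1 TPM, with a list median of 305 ± 60.2 TPM. Of the iron and redox genes 11 of 12 did, all except Nqo1 (0.250 TPM); the transferrin receptor Tfrc had 202 ± 75.4 TPM and the iron exporter Slc40a1 118 ± 9.28 TPM. All 14 sterol and lipid genes did as well, led after Apoe by the lipase Lpl (223 ± 73.2 TPM), the fatty acid receptor Cd36 (122 ± 42.7 TPM) and the cholesterol exporter Abca1 (120.2 ± 31.2 TPM). The 18 glycolysis genes were all present, with Gapdh at 233 ± 11.4, Aldoa at 120.3 ± 0.134, Pkm at 88.8 ± 12.8 and Ldha at 78.8 ± 3.87 TPM.

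The list of class I antigen presentation genes had a median of 32.6 ± 0.976 TPM and that of class II genes 14.4 ± 3.83 TPM. All 10 class I genes reached 1 TPM, with B2m (the light chain, 1413 ± 79.3 TPM), H2-D1 (963 ± 184 TPM), H2-K1 (716 ± 171 TPM) and Tapbp (94.8 ± 18.6 TPM) highest. For class II, 9 of 10 did, with Cd74, the invariant chain, at 82.2 ± 25.2 TPM, the costimulatory receptor Cd40 at 43.0 ± 5.81 TPM, H2-Aa at 27.4 ± 9.90 TPM and H2-Eb1 at 20.1 ± 6.34 TPM; the class II transactivator Ciita had 0.475 TPM. Of 11 alternative activation genes 5 reached 1 TPM, and 8 on the scale over nuclear-encoded protein-coding genes; they included the mannose receptor Mrc1 (99.9 ± 26.9 TPM), the interleukin 4 receptor Il4ra (16.98 ± 4.19 TPM), Pparg (13.1 ± 0.290 TPM) and Clec10a (7.68 ± 1.31 TPM). Cell cycle genes reached 1 TPM in 7 of 16 cases, with Pcna at 62.7 ± 5.81, Mki67 at 17.6 ± 0.163, Cdk1 at 3.81 ± 0.467 and Top2a at 3.38 ± 0.643 TPM. That count is close to the threshold, since 15 of the 16 reached 0.5 TPM and all 16 reached 1 TPM on the scale over nuclear-encoded protein-coding genes.

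Most markers of other cell types were below 1 TPM. Of 12 neutrophil markers 4 reached 1 TPM, S100a9 (17.2 ± 0.240 TPM), S100a8 (9.73 ± 0.686 TPM), Mmp8 (3.55 ± 0.658 TPM) and Ngp (2.32 ± 1.09 TPM). Of 10 dendritic cell markers 3 did, Bst2, which macrophages also express (83.0 ± 2.66 TPM), Itgax (1.04 ± 0.219 TPM) and Ccr7 (1.02 ± 0.445 TPM); replicate 1 alone had 1. Among 10 osteoclast markers 4 did, the proton pump subunit Atp6v0d2, also on the lysosome list (52.6 ± 10.04 TPM), Tnfrsf11a (11.1 ± 2.58 TPM), Acp5 (9.23 ± 3.06 TPM) and Nfatc1 (7.48 ± 0.0141 TPM). A single gene reached 1 TPM on the T and NK cell list (Cd4, 17.2 ± 3.37 TPM), the B and plasma cell list (Ighm, 2.41 ± 0.226 TPM), the erythroid and platelet list (Pf4, 161 ± 25.4 TPM) and the stromal and endothelial list (Kdr, 1.48 ± 0.0919 TPM), each of 12 genes. None of 10 mast cell and basophil markers did, the highest being Gata2 at 0.250 TPM. On the scale over nuclear-encoded protein-coding genes 6 dendritic, 3 B cell, 2 erythroid and 1 mast cell marker reached 1 TPM.

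Of 10 long noncoding RNAs known to stay in the nucleus 4 reached 1 TPM. They were Malat1 (chromosome 19, 5795690 to 5802672; 479 ± 453 TPM), the paraspeckle RNA Neat1 (chromosome 19, 5824708 to 5845478; 39.7 ± 35.2 TPM), Xist, which silences an X chromosome (3.23 ± 3.12 TPM), and Firre (1.22 ± 0.700 TPM). Of 10 members of the list named cytoplasmic noncoding RNAs 9 reached 1 TPM, all except Dancr (0.195 TPM). The list includes Rmrp, and where in the cell its RNA lay was not tested. Norad, listed under its clone name 2900097C17Rik, had 43.2 ± 1.202 TPM. Of 9 members of the list named small nuclear noncoding RNAs 6 did. Below Rn7sk and Rpph1 came Rnu1a1 (256 ± 199 TPM), whose posterior SD was 62.6% and 58.4% of its count in replicates 1 and 2. Then came Rnu12 (12.2 ± 11.5 TPM, from 2 and 8 counts), while the members Rnu11, Rny1 and Rny3 had 0 counts in both libraries. Among the sex-linked genes, Xist had 1760 and 7317 expected counts, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both libraries. A count of 0 allows at most 3 counts per library.

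All 12 reference genes reached 1 TPM. The cytoskeletal gene Actb had 1645 ± 303 TPM, the translation elongation factor Eef1a1 1384 ± 129 TPM and the prolyl isomerase Ppia 336 ± 32.7 TPM; B2m and Gapdh are given above. As for the levels of lists, those of the NF-kB, feedback, cytokine, chemokine, immediate-early, interferon, other pattern receptor, macrophage, lysosome, iron, class I, sterol, glycolysis and reference genes lay at percentile 100 in both libraries. TLR4 signalling (99.98 and 100), class II (99.86 and 99.98) and cytoplasmic noncoding genes (100 and 99.92) lay nearly as high. The small nuclear list lay at percentiles 77.9 and 98.9, cell cycle genes at 79.5 and 79.9 and alternative activation genes at 77.7 and 73.1. Nuclear-retained RNAs (53.2 and 57.2), neutrophil (51.0 and 59.0), dendritic (52.6 and 56.8) and osteoclast markers (57.75 and 61.9) lay near the middle. Their list medians were only 0.35, 0.2975, 0.30 and 0.48 TPM, averaged over the libraries. The random lists, also those for noncoding RNAs, were drawn from all protein-coding genes, detected or not. The lists of T and NK, B, erythroid, mast and stromal cell markers and of sex-linked genes lay below percentile 50 in both libraries.

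The replicates were compared with each other to see how precise a level is. Their biological coefficient of variation was 0.176 over 13398 genes, with a chi-square index of 124 against 1 for sampling noise alone, so they were not counted as 1 library deposited under both labels. The index does not tell whether they came from separate cultures. Across the 9154 detected genes log2 TPM correlated with Pearson's r = 0.966 and TPM with Spearman's rho = 0.979; these are across genes, which are not independent replicates. Of 10091 genes with a mean count of 100 or more, 161 (1.60%) differed by more than 2-fold after TMM scaling, 132 higher and 29 lower in replicate 2. At a mean count of 10 or more this was 931 genes, and at 500 or more 59. Of the 132 higher, 25 were nuclear-encoded protein-coding genes and 35 were TEC genes, models that the annotation lists as still to be experimentally tested. Of the 29 lower, 23 were nuclear-encoded protein-coding genes and 8 were on the interferon list. With 2 libraries of 1 group no test between conditions can be made, and these ratios compare libraries, not conditions.

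The genes farthest apart were mainly noncoding on the higher side. Gm15725, a transcribed pseudogene (chromosome 16, 37882542 to 37883631), had 0 counts in replicate 1 and 237 in replicate 2. That was 90.3-fold higher against a floor of 3 counts in replicate 1, without the counting error of replicate 2. The lower end of the 95% counting interval of its log2 ratio was 6.19. Its posterior SD in replicate 2 was 15.7% of the count, and pseudogenes share reads with their parent genes. Gm26917 (chromosome 17, 39843013 to 39846341), annotated as a lincRNA, had 5007 and 31636 counts, a log2 ratio of 2.85 (95% counting interval 2.81 to 2.90). Which RNA its reads came from was not tested. Gm26522 (2.64), the TEC gene Gm37352 (2.61) and the pseudogene Gm21370 (2.59) followed. On the lower side, Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), had 35410 and 7282 counts, a log2 ratio of -2.09 (-2.12 to -2.05), and Ifit1 (chromosome 19, 34640871 to 34650009) had 32766 and 8030 counts, a log2 ratio of -1.83 (-1.87 to -1.80). Zbed6 (-2.99) and Gm14296 (-2.07) are uncertain, with posterior SDs in replicate 2 of 287% and 121% of the count. So is Gm26669 (-1.87), which overlaps Zfp36l1 on the other strand, since the strand used in counting is not given in the sources used here.

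By list, interferon genes were lower in replicate 2 and nuclear-retained RNAs higher. The median log2 ratio of the interferon list was -0.73, with 19 of 20 members lower, all but Irf1, and none of 10000 random lists matched on expression lay lower. Ifnb1 had a log2 ratio of -1.19 (counting interval -1.26 to -1.12), Rsad2 -1.46 (-1.47 to -1.44) and Isg15 -1.08 (-1.14 to -1.03). Chemokines lay lower too, with a median of -0.31, 12 of 16 members lower and percentile 0.01; removing a trend with transcript length and GC content, an alternative chosen after the data were seen, left -0.19 and percentile 0.05. In contrast, all 7 nuclear-retained RNAs with a mean count of 10 or more were higher in replicate 2. Of the 10 listed, 4 reached 1 TPM. The list's median was 2.02 (1.31 in the second quantification), at percentile 100. Malat1 was at 2.23 (2.22 to 2.24), Neat1 at 2.02 (1.98 to 2.06) and Xist at 2.25 (2.18 to 2.33). All 4 measured small nuclear RNAs were higher, with a median of 1.02 and percentile 99.8 (0.58 in the second quantification, where the list was no longer among the highest 2.5% of random lists).

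**Figure D3:**
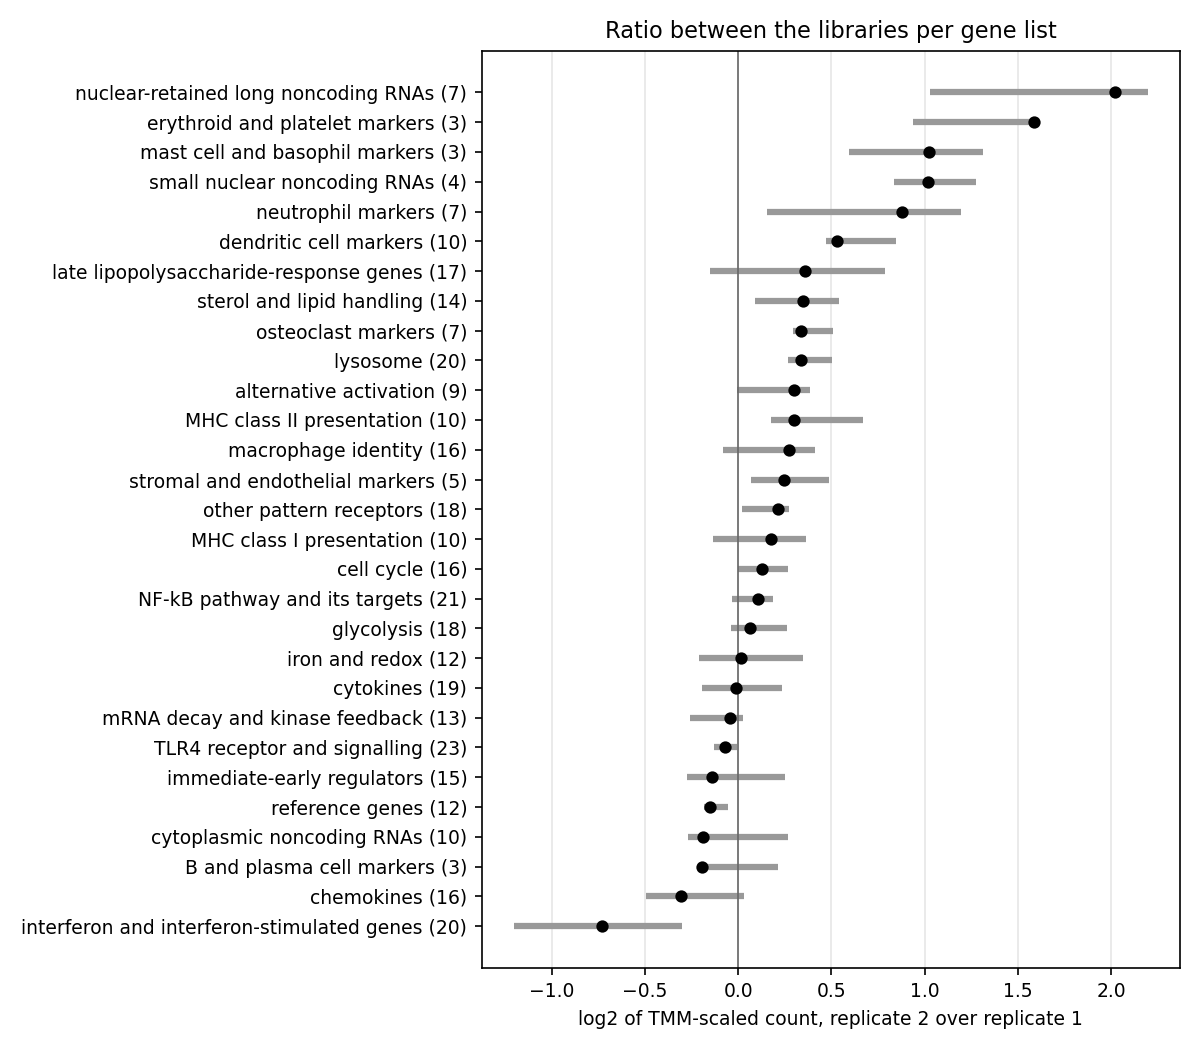
Median (points) and interquartile range over members (bars) of the log2 ratio of TMM-scaled counts, replicate 2 over replicate 1, for each list with 3 or more measured members (number in brackets). The interferon list lies lowest at -0.73 and the nuclear-retained RNAs highest at 2.02; the glycolysis and B cell medians change sign in the second quantification, and the iron median there and with library totals.

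Smaller shifts ran through the macrophage lists. Most lists with a percentile lay among the lowest or highest 2.5% of random lists. Because random lists draw genes independently, a small shift shared by a list's members can reach that range. Lysosome genes had a median log2 ratio of 0.34 (19 of 20 higher in replicate 2, percentile 99.99), sterol and lipid genes 0.35 (11 of 14, 99.98), class II genes 0.30 (9 of 10, 99.97), alternative activation genes 0.30 (6 of 9, 98.6) and macrophage identity genes 0.27 (11 of 16, 99.9). Class I genes had 0.18 (6 of 10, 97.8), osteoclast markers 0.34 (6 of 7, 97.7), other pattern receptors 0.21 (14 of 18, 99.85) and late genes 0.36 (10 of 17, 99.94). Reference genes had -0.15 (11 of 12 lower, 1.77), immediate-early regulators -0.14 (9 of 15 lower, 1.40) and cytoplasmic noncoding RNAs -0.19 (7 of 10 lower, 2.37). The cytoplasmic list counts 7SL under both Rn7s1 and Rn7s2, identical copies at -0.26 each. It counts Rmrp by its more abundant gene, at 1.47, and 2 of its members were over 2-fold higher. With the length and GC trend removed, the reference median was -0.035 (percentile 24.5) and the cytoplasmic noncoding median -0.063 (15.4), neither among the lowest 2.5% of random lists. The NF-kB (0.11), TLR4 (-0.07), feedback (-0.05), cytokine (-0.01), cell cycle (0.13), glycolysis (0.06) and iron (0.01) medians were in neither the lowest nor the highest 2.5% of random lists. Neutrophil markers had a median of 0.88 (5 of 7 higher, 99.9) and erythroid markers 1.58 (3 of 3, 98.6). Dendritic markers had 0.53 (8 of 10, 98.7), mast cell markers 1.02 (3 of 3, 88.9) and stromal markers 0.25 (4 of 5, 65.2). Except for the neutrophil list, most of these members were below 1 TPM. In the second quantification the late, other pattern receptor, cytoplasmic noncoding, erythroid and osteoclast lists were no longer among the outermost 2.5% of random lists. B cell markers had -0.20 (2 of 3 lower, percentile 14.9), which was 0.68 in the second quantification, and Cd4, the only T cell marker counted, had 0.19.

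The second deposited quantification of the same libraries gave the same leading transcript for most genes. Among genes at 1 TPM or more with at least 2 transcripts, the most abundant transcript was the same in 7356 of 8185 genes in replicate 1 (89.9%, 95% Clopper-Pearson interval 89.2 to 90.5) and 7279 of 8186 in replicate 2 (88.9%, 88.2 to 89.6). Spearman's rho between the quantifications was 0.746 and 0.714 across transcripts and 0.971 and 0.970 across genes, which are not independent replicates.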

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

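The 4 tests of explanations for the nuclear-retained RNAs and the interferon genes were chosen only after the result was seen. Signal above the 3 counts that a count of 0 allows was found in sequences outside the comparisons of gene lists and single genes. The phiX174 sequence, the genome of a bacteriophage used as a sequencing control, held 139738 expected counts in replicate 1 and 102278 in replicate 2 of the first quantification. The spike-in ERCC-00099 held 6 counts in replicate 2 of the second quantification, and the ERCC spike-ins together 0 in the first. The processed pseudogene Gm12896 (chromosome 4, 122122847 to 122123072) held 2412420 and 3729720 counts in the second quantification and 0 in the first. Gm23935, annotated as a microRNA (chromosome 16, 11144125 to 11144181), held 365526 and 376473 counts in the second and 0 in the first. With Gm12895, whose mean TPM equalled that of Gm12896, and Gm24245 and Gm24270, whose mean TPM equalled that of Gm23935, these 5 genes, chosen after their values were seen, took 56.1% of the TPM of the second quantification in replicate 1 and 67.8% in replicate 2, but 8.98% and 13.7% of its counts. They enter the class shares of the second quantification, and how reads were divided among genes of equal TPM is uncertain.

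Nuclear-retained long noncoding RNAs were higher in replicate 2, with a median log2 ratio of 2.02 and all 7 measured members higher. Removing a trend of the ratio with transcript length and GC content left the median at 2.01 (interquartile range 1.16 to 2.19). That trend was fitted on protein-coding genes and was small. Median log2 ratios ran from -0.16 to 0.033 over bins of length and from -0.11 to 0.072 over bins of GC content. Removing it could therefore hardly move this list, and whether noncoding RNAs follow another trend was not tested. More nuclear RNA in the replicate 2 library is a candidate explanation: transcripts annotated with a retained intron took a higher share of their gene's count in replicate 2 in 1949 of 2402 genes (81.1%, Clopper-Pearson interval 79.5 to 82.7). Transcripts annotated for nonsense-mediated decay did so in 52.1% of 1223 genes (49.2 to 54.9), and genes are not independent replicates. All 13 mitochondrial mRNAs, which are not encoded in the nucleus, were also higher in replicate 2, with a median log2 ratio of 0.97. More nuclear RNA does not by itself cover that rise. With 1 group no biological explanation was tested, so whether fractionation or the cells differed was not tested.

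Interferon and interferon-stimulated genes were lower in replicate 2, with a median log2 ratio of -0.73. After the same length and GC trend was removed the median was -0.69 (interquartile range -1.15 to -0.26). The trend as fitted over protein-coding genes was thus too small to account for the ratio of this list. Whether replicate 2 stood earlier in the response cannot be told apart with these lists, since the late-response list had a median of 0.36 with 10 members higher and 7 lower. The immediate-early list, also part of this test, had a median of -0.14 with 6 members higher and 9 lower. No other biological explanation was examined, since the design has only 1 group.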

How the results depend on the processing

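Counting only nuclear-encoded protein-coding genes, the ratios of RNA classes, the removal of a length and GC trend, a limit on the posterior SD of mitochondrial mRNAs and the criterion for calling a list apart were chosen after the data were seen; the other alternatives were not. No paired analysis was possible because there was only 1 group. Leaving out a replicate leaves 1 library, whose value lies within 1 SD of the mean of 2 by construction, so it says nothing about stability for values with an SD. Dispersion has no SD, so any other value counts as different. Apart from the dispersion, the list ratios, except that of iron genes with library totals, kept their sign with DESeq2 size factors and library totals, and the count over 2-fold was 164 and 152. Where no construction is named below, the cause was not tested.

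The number of genes detected at 1 TPM or more ran from 9061 to 9199 with a replicate left out and was 5091 at 5 TPM, 10347 at 0.5 TPM, 7641 in the second quantification and 12849 for at least 10 counts in each library. At 5 TPM fewer list members counted by construction: 2 cell cycle genes, 2 nuclear-retained RNAs, 2 neutrophil markers, 1 dendritic marker and 0 B cell, stromal and sex-linked genes. At 0.5 TPM there were 15 cell cycle genes and 2 erythroid and platelet markers. TPM rescaled over nuclear-encoded protein-coding genes, which raises every value, gave 16 late genes, 16 cell cycle genes, 8 alternative activation genes, 6 dendritic, 3 B cell, 2 erythroid and 1 mast cell marker. The second quantification gave 1 dendritic, 1 mast cell and 0 stromal markers, and dendritic markers ran from 1 to 3 with a replicate left out.

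Against a background of genes at 1 TPM or more, with lists limited likewise, the percentile of the list median was 99.93 for feedback genes, 99.99 for cytokines, 96.9 for TLR4 signalling, 99.4 for other pattern receptors, 86.2 for alternative activation, 99.96 for class I, 97.2 for class II, 99.88 for sterol genes, 13.1 for the cell cycle, 92.4 for nuclear-retained RNAs, 99.0 for cytoplasmic noncoding RNAs, 47.7 for neutrophil, 0.04 for dendritic and 70.3 for osteoclast markers. Lists with fewer than 3 such members gave no value. In the second quantification it was 80.1 for alternative activation, 78.0 for the cell cycle, 66.4 for nuclear-retained RNAs, 49.7 for dendritic markers, 20.8 for stromal markers and 36.7 for sex-linked genes.

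The early minus late list difference was 1.56 among members at 1 TPM or more, which drops the lowest late genes by construction, and ran from 3.72 to 4.66 with a replicate left out; elsewhere it ran from 3.59 to 4.25. The replicate dispersion, as a coefficient of variation, was 0.1762 with DESeq2 size factors, 0.1753 with library totals, 0.181 over genes with any count, 0.144 at a mean count of 100 or more and 0.258 in the second quantification. Genes differing over 2-fold between the libraries numbered 931 at a mean count of 10 or more, 59 at 500 or more, 489 at 1.5-fold, 259 in the second quantification and 48 among nuclear-encoded protein-coding genes. Counting error is larger at low counts, so depth limits the ratios of genes with few counts.

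The second quantification kept the sign of these list ratios but not their place among the outermost 2.5% of random lists: 0.13 for late genes, 0.048 for other pattern receptors, -0.20 for cytoplasmic noncoding RNAs, 0.58 for small nuclear RNAs, 1.48 for erythroid and 0.38 for osteoclast markers. With the length and GC trend removed, these list ratios kept their sign but not that place, -0.063 for cytoplasmic noncoding RNAs and -0.035 for reference genes; the cytokine ratio, set apart in neither, went from -0.01 to 0.11. The histone mRNA ratio was 0.13 and turned to -0.024 in the second quantification. As percent of counts, which drops the division by length, the class shares were 82.0 for other protein-coding mRNAs, 14.2 for small noncoding RNAs, 0.954 for long noncoding RNAs, 0.185 for histones and 0.000912 for other biotypes. In TPM of the second quantification they were 9.10, 51.4, 0.427, 0.0385 and 0.000697, with 38.1 for pseudogenes, 0.710 for ribosomal protein mRNAs and 0.229 for mitochondrial RNAs; Gm12895 and Gm12896 are among those pseudogenes. The leading transcript was the same in 90.3% of genes at 10 TPM or more and in 88.9% to 89.9% with a replicate left out. Of the single genes' TPM, 141 differed by over 1 SD on the rescaled TPM and 118 in the second quantification, in which the 5 short RNAs take most of the total.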

Other observations

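The gene classes in this part, and their comparisons, were chosen only after the result was seen. All 13 mitochondrial mRNAs were higher in replicate 2, with a median log2 ratio of 0.97 and a range of 0.19 to 1.43; mt-Co1, a subunit of cytochrome c oxidase (chromosome M, 5328 to 6872), had 638.9 and 1265 TPM. The ratios of mt-Co2, mt-Atp6 and mt-Co3 are uncertain, with posterior SDs in replicate 1 of 307%, 99.0% and 48.2% of the count. Over the other 10, with posterior SDs of 15% or less, the median was 0.94 and all were higher. All 78 measured ribosomal protein mRNAs were lower in replicate 2, with a median of -0.39 and a range of -0.66 to -0.17; with the length and GC trend removed the median was -0.27, and all 78 were still lower. Histone mRNAs had a median of 0.13 (47 of 69 higher), which was -0.024 in the second quantification.

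Short nuclear RNAs and unassigned transcripts were higher in replicate 2. Of 24 measured snRNA genes, which act in splicing, 23 were higher with a median log2 ratio of 1.62, and all 21 snoRNA and scaRNA genes, which guide RNA modification, were higher with a median of 1.26. The limit on the posterior SD was not applied to these classes, so their genes need not be separately measured RNAs. Of 403 TEC genes 367 were higher with a median of 1.65. These medians kept their sign with DESeq2 size factors, library totals and the second quantification, where they were 1.58, 1.24 and 1.33. Gm26917 and its neighbour Gm42418 (chromosome 17, 39846958 to 39848788), the latter chosen after its values were seen, had log2 ratios of 2.85 and 2.21. Both are annotated as lincRNAs, and which RNA their reads came from was not tested.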
